A study of Mus musculus with 4 samples.

How the data were processed

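Liver RNA of FVB/NJ mice, an inbred laboratory strain, was measured on 4 single-colour filter arrays. Of these, 2 were labelled control and 2 came from animals given 4-nonylphenol (4-NP) for 32 weeks. No treatment time was recorded for the control samples. The labels do not give the dose or route of 4-NP or the sex of the mice. Each array carried 1 sample. Groups and replicate numbers were taken from the sample titles.

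Per the labels, RNA enriched for polyadenylated transcripts was reverse transcribed with a radioactive nucleotide, hybridised to a Clontech Atlas mouse cDNA array and read with a phosphorimager. Per the labels, the authors subtracted a local background from each spot intensity and divided the result by the mean intensity of all spots on that array. The deposited intensity is therefore a linear value relative to the array mean. The column means of the deposited table were 0.993, 0.990, 0.991 and 0.976 for control 1, control 2, 4-NP 1 and 4-NP 2. The medians were 0.888, 0.846, 0.815 and 0.793. The table held 1185 probes with no value at or below 0, and no detection call or spot flag was used here. The software version was not given in the sources used here. Arrays have no read depth, so the number of arrays limits the precision.

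The deposited table does not pair its probe codes with genes. Of the 1185 codes, 0 matched a gene identifier, symbol, transcript accession or Ensembl identifier of the mouse gene table, and 16 coincided with gene synonyms. These coincidences were not used, because a short array code does not identify a gene. For the same reason the 21 gene lists fixed in advance, the estrogen receptor gene and the housekeeping genes were not analysed here. Probe codes are given as deposited, and genomic positions are not given.

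Intensities were transformed as log2(value + 0.735), where 0.735 was the 25th percentile of all values on the 4 arrays. The 1060 probes whose mean over the 4 arrays exceeded the same value were tested and 125 dimmer probes were left out. Log2 fold changes are on this offset scale, which understates the change of dim probes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), 4-NP minus control, with Benjamini-Hochberg adjustment and a threshold of 0.05. The group means left 2 residual degrees of freedom, and the fitted prior added 6.18. Probes were also counted when their group means differed at least 2-fold on the deposited scale and both 4-NP values lay on one side of both control values. Under the rule fixed for naming, probes whose 4-NP values both lay above or both below the control values were ranked by log2 fold change. Because no genes could be named, the first 2 in each direction are given in place of the first 12.

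The test was checked on 50 simulated data sets of 1060 probes with 200 changed probes each, with means and spread taken from these arrays. It called 5.31% of the probes changed 1.5-fold, 27.4% of those changed 2-fold and 68.4% of those changed 3-fold, and 0.374% of the unchanged probes. The median error of the fold change was at most 0.0053 on the log2 scale in these sets.

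The choices of test, samples, offset, filter, naming rule and alternatives were made before the data were examined. The alternatives were 3 other treatments of low values, quantile, median and cyclic loess normalization, 2 other filters on dim probes, leaving out each array, the replicate number as a block, 2 other variance priors, another adjusted p threshold and 2 other fold thresholds. Subtracting the 5th percentile of each array, and testing only probes with a mean of at least 1.5, were added after seeing the data. No evidence was found that the replicate numbers pair the samples, and nothing in the labels ties equal numbers together. The difference between replicates 1 and 2 in control correlated with that in 4-NP at r = 0.036 across the 1060 probes. Noise lowers such a correlation, so it does not exclude a pairing.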

Results

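Gene expression was measured in the livers of FVB/NJ mice after 32 weeks of 4-NP, an alkylphenol formed from nonionic surfactants that is known as a weak estrogen receptor agonist. There were 2 control arrays and 2 4-NP arrays, each with 1185 probes. The labels state that each RNA came from a mouse liver sample but do not say that every array came from a different animal, so the p-values measure the spread between these samples only.

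Most probes lay in a narrow band just below the array mean, and 93.2% of all values were between 0.5 and 1.5 times that mean. The 5th to 95th percentile ran from 0.683 to 1.46 on control 1, from 0.626 to 1.68 on control 2, from 0.598 to 1.82 on 4-NP 1 and from 0.639 to 1.58 on 4-NP 2. Averaged over the 4 arrays, 63 probes (5.32%) reached at least 1.5 times the array mean. The highest value was 7.24 on control 1, 5.93 on control 2, 7.94 on 4-NP 1 and 10.6 on 4-NP 2. The 12 brightest probes of each array held 5.71% and 5.62% of the summed intensity on the control arrays, and 6.50% and 8.70% on 4-NP 1 and 4-NP 2. The median was lower on both 4-NP arrays (0.815 and 0.793) than on both control arrays (0.888 and 0.846). With 2 arrays against 2, the smallest p that a two-sided exact permutation test of such a value can give is 0.333.

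**Figure D1:**
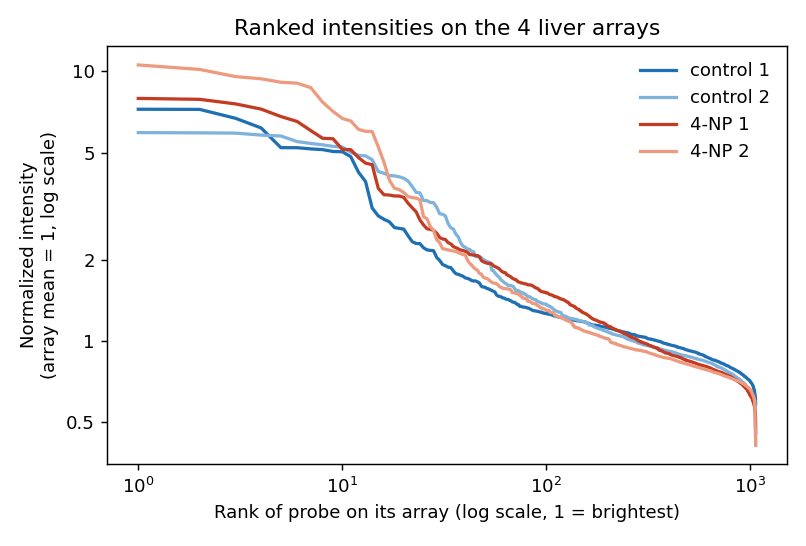
Normalized intensity (array mean = 1, log axis) against rank (log axis) for the 1060 tested probes on each of the 4 arrays, one line per array. The lines lie close together over most ranks and part at the bright end, where the highest value is 5.93 on control 2 and 10.6 on 4-NP 2.

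Replicate arrays resembled each other hardly more than arrays of different groups did. Across the tested probes, which are not independent replicates, Pearson's r of log2 values was 0.782 between the control arrays and 0.670 between the 4-NP arrays. Between groups, control 1 correlated at 0.560 with 4-NP 1 and at 0.778 with 4-NP 2, and control 2 at 0.618 and 0.810. Each control array was thus closer to 4-NP 2 than 4-NP 1 was. The mean within-group r exceeded the mean between-group r by 0.035. The SD of the log2 difference was 0.218 between the control arrays and 0.301 between the 4-NP arrays. Rank correlations were lower, at 0.456 between the control arrays and 0.129 between the 4-NP arrays. Between groups they were 0.029 and 0.330 for control 1 with 4-NP 1 and 4-NP 2, and 0.209 and 0.468 for control 2. Among the 63 bright probes they were 0.830 and 0.607 within groups. Between groups they were 0.533 and 0.775 for control 1 with 4-NP 1 and 4-NP 2, and 0.494 and 0.737 for control 2.

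The comparison of 4-NP with control livers asked which transcripts differ after long exposure. No probe passed the threshold among the 1060 tested, with a lowest adjusted p of 0.737 in limma. At an unadjusted p under 0.05 there were 47 probes, of which 9 were higher and 38 lower in 4-NP, and chance alone gives 53. The count of calls depended on which 4-NP array was set against the control pair. Without 4-NP 2, 38 probes passed (35 higher, 3 lower), and without 4-NP 1, 8 passed (all lower). The called probes differed entirely between these cases, and in both the spread came from the control arrays alone. The split into 9 and 38 depended on the scaling and on single arrays. It was 29 higher and 20 lower with each array divided by its median, 22 and 31 after quantile normalization, and 18 and 23 after cyclic loess. It was 30 and 33 without 4-NP 1, 111 and 78 without 4-NP 2, 2 and 21 without control 1, and 2 and 45 without control 2. With the 5th percentile of each array subtracted, an alternative added after seeing the data, it was 35 and 33. The median absolute log2 fold change was 0.12, and the median half-width of the 95% interval was 0.30. In simulated data of the same size, with 200 changed probes per set, 27.4% of the 2-fold changes were called. A change of that size in a single probe was thus often not detectable with these arrays. The simulated 2-fold changes were recovered at full size on the log2 scale (median error -0.0015). A 2-fold difference of deposited intensities can be smaller on the offset scale, as for a probe with a ratio of 0.499 and a log2 fold change of -0.57. The 27.4% may therefore overstate how often such a difference would be called.

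The 4-NP values lay wholly above or wholly below the control values at 422 of the 1060 probes (39.8%, against 33.3% by chance). These were higher in 4-NP at 106 probes and lower at 316. With each array divided by its median, the filter kept 1049 probes, and of these 204 were separate and higher and 189 separate and lower. Group means at least 2-fold apart with such separation were found for 5 probes, 3 higher and 2 lower in 4-NP. Another 10 probes had means at least 2-fold apart with overlapping groups. All of these except MA161 were high on 4-NP 1 alone, with 4-NP 2 no higher than the brighter control value. The exception was lower in 4-NP and was high on control 2 alone. Leaving out one array changed the count of 2-fold probes with separate groups. It was 19 without control 1, 22 without control 2, 11 without 4-NP 1 and 46 without 4-NP 2. The 46 include the probes above that were high on 4-NP 1 alone, since their groups separate once 4-NP 2 is left out. With 2 arrays against 1, chance separates the groups at 66.7% of probes, which raises these counts by construction. Whether it accounts for their size was not tested.

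**Figure D2:**
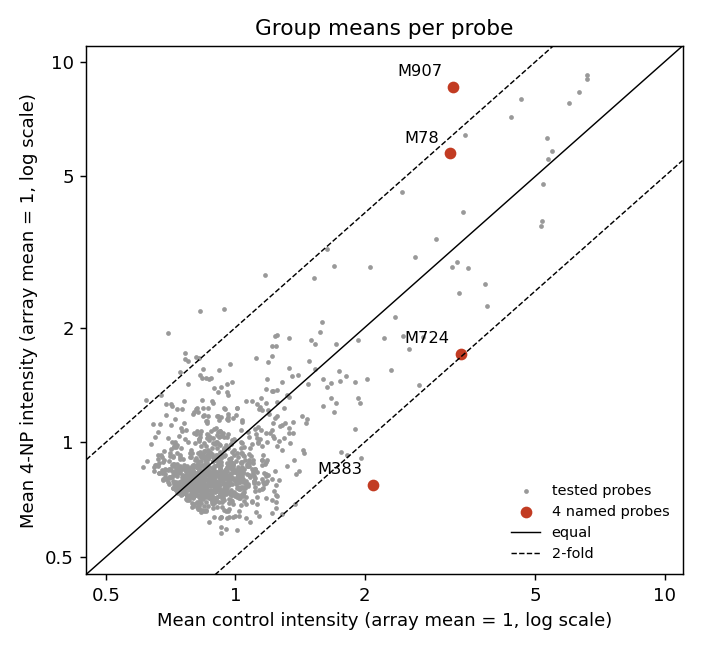
Mean 4-NP intensity against mean control intensity for the 1060 tested probes (grey points, both axes log, array mean = 1), with lines at equality and 2-fold, and the 4 named probes in red. M907 lies above the upper 2-fold line at 2.66-fold, and M383 below the lower one at a ratio of 0.369.

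The largest positive log2 fold change was at probe M907, one of the brightest on the arrays. Its intensity was 8.57 ± 1.41 (SD, n = 2) in 4-NP and 3.22 ± 1.47 (SD, n = 2) in control, a ratio of 2.66. The log2 fold change was 1.28 with a standard error of 0.33 and a 95% interval from 0.53 to 2.03, and limma gave an unadjusted p of 0.0043 and an adjusted p of 0.737. It passed the threshold after quantile normalization (adjusted p = 0.026 in limma) and when only the 63 bright probes were tested (adjusted p = 0.024 in limma), a filter chosen after its values were seen. Probe M78, next among the probes with separate groups, measured 5.74 ± 1.34 (SD, n = 2) in 4-NP and 3.16 ± 1.33 (SD, n = 2) in control, with a log2 fold change of 0.76 ± 0.38 (SE) and the same adjusted p of 0.737 in limma. Its log2 fold change was 0.40 without control 1.

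The lowest fold change was at probe M383, with 0.773 ± 0.030 (SD, n = 2) in 4-NP and 2.10 ± 1.65 (SD, n = 2) in control. Its control mean rested on control 2, which measured 3.26 where control 1 measured 0.933. The log2 fold change of -0.78 ± 0.37 (SE) became -0.15 without control 2 and -1.41 without control 1. Probe M724 measured 1.71 ± 0.0036 (SD, n = 2) in 4-NP and 3.35 ± 1.06 (SD, n = 2) in control, a log2 fold change of -0.72 ± 0.40 (SE) that was -0.45 without control 2. Both had an adjusted p of 0.737 in limma. The remaining 3 probes at least 2-fold apart with separate groups fell outside the 2 named per direction. Their ratios were 2.11, 2.09 and 0.499. In all 5 probes except M907 the lower group lay within the band that most probes occupied, at control means of 0.777 and 0.620 for the first and second of these 3, and at 4-NP means of 0.688 for the third and 0.773 for M383. The size of such a fold depends on the background taken off, and the log2 fold change of M383 was -1.90 with the 5th percentile of each array subtracted.

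**Figure D3:**
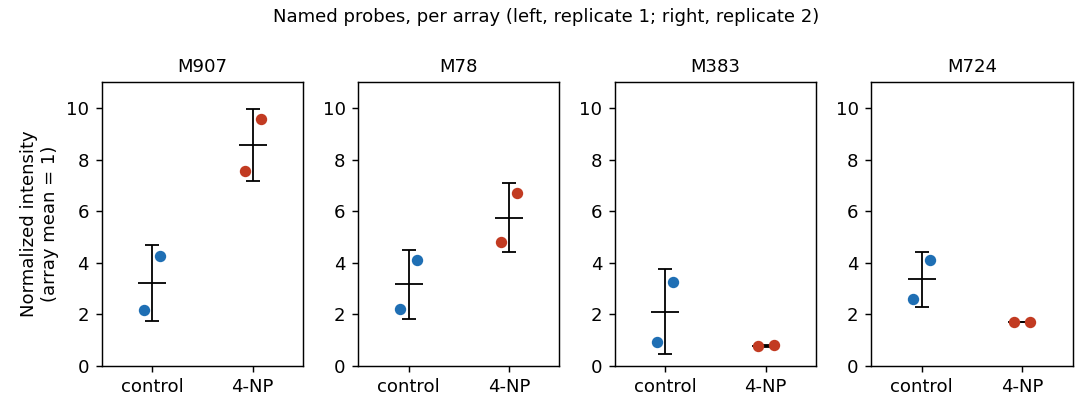
Normalized intensity (array mean = 1, linear axis from 0) of the 4 named probes on each array, points for replicates 1 and 2 and bars for the mean and SD of each group (n = 2). M907 measured 7.57 and 9.56 in 4-NP against 2.18 and 4.25 in control, while the control values of M383 spread from 0.933 to 3.26.

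The 63 bright probes were divided between directions, with 35 higher and 28 lower in 4-NP and a median log2 fold change of 0.05. After quantile normalization the balance turned, to 27 higher and 36 lower with a median of -0.06, and with each array divided by its median it was 38 and 25 with a median of 0.15. Separation of the groups was seen at 30 of them, 20 higher and 10 lower. The other 997 tested probes had a median log2 fold change of -0.05. At an unadjusted p under 0.05 in limma there were 4 bright probes, all 4 higher in 4-NP on the deposited scale. The top of the intensity range lay higher on both 4-NP arrays. The fourth brightest value was 6.17 on control 1, 5.80 on control 2, 7.25 on 4-NP 1 and 9.39 on 4-NP 2. M907 and M78 were likewise higher on 4-NP 2 than on 4-NP 1. Their log2 fold changes were 1.01 and 0.62 after quantile normalization, against 1.28 and 0.76 without it. How much of their rise this difference between arrays accounts for was not tested.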

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

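The count of 0 called probes held under 14 of the 18 alternatives. It became 4 (2 higher and 2 lower) after quantile normalization, M907 among them, and 1 (M907) when only probes with a mean of at least 1.5 were tested, the latter chosen after seeing the data. Leaving out one array gave 0 to 38 calls. Without 4-NP 1 there were 8, all lower, and without 4-NP 2 there were 38, of which 35 were higher. The probes called in these fits differed from each other and from those called after quantile normalization. In these fits the lone array was assumed to vary like the control arrays. Their SD of log2 differences (0.218) was below that of the 4-NP arrays (0.301). The number at an unadjusted p under 0.05 was 5 among the probes with a mean of at least 1.5, and otherwise ranged from 23 without control 1 to 189 without 4-NP 2. The count of 5 probes at least 2-fold apart became 9 after quantile normalization, 9 with each array divided by its median, 75 at 1.5-fold, 0 at 3-fold, 244 with the 5th percentile of each array subtracted (added after seeing the data), 1 among probes with a mean of at least 1.5 and 11 to 46 without one array. Chance separates the groups more often with 2 arrays against 1 (66.7% against 33.3% of probes), and otherwise the cause was not tested. The excess of the within-group over the between-group correlation (0.035) was at most 0.081, among probes with a mean of at least 1.5. Its sign turned after cyclic loess (-0.0027). It stayed within 1 SD of the between-group values under all 10 alternatives run, but that SD (0.121) is larger than the excess itself, so this shows little. The 4 named probes were chosen for separate groups, which fixes their direction under most alternatives. M907 ranged from 0.89 to 1.71 in log2 fold change, M78 from 0.40 to 1.12, M383 from -1.90 to -0.15 and M724 from -1.17 to -0.45. Under the replicate block, which the labels and the check of paired deviations gave no ground for, 0 probes were called and 41 reached an unadjusted p under 0.05. Signal over background was not measured here.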

Other observations

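The patterns below were picked out in these same data, so no test of them is independent support. The test of the brightness ratios on all 4 arrays and the test of neighbouring probe codes were also chosen after the pattern they address was seen.

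The first pattern was the excess of probes lower in 4-NP, 80.9% of the 47 at an unadjusted p under 0.05. Among probes at that p, the excess was not seen with either 4-NP array alone, and it remained without either control array. The fits with a single 4-NP array take their spread from the control arrays alone. Over all tested probes the median log2 fold change was negative in each case. It was -0.063 without 4-NP 1, -0.061 without 4-NP 2, -0.026 without control 1 and -0.046 without control 2, against -0.043 with all 4 arrays. Scaling to the array mean, which a few bright spots move, is a candidate explanation, because the brightest 12 probes held a larger share of the signal on the 4-NP arrays. That basis is mainly 4-NP 2 (8.70%), since the share on 4-NP 1 (6.50%) was closer to those on the control arrays (5.71% and 5.62%). With each array divided by its median, the share of probes lower in 4-NP was 40.8%. That scaling centres the fold changes by construction, so it shows that the balance depends on the centre chosen and not which centre is right, and the explanation stays open. The 4 arrays can be split into 2 and 2 in only 3 ways, too few for a share under 0.05. The real split gave 47 probes and the highest other gave 60, with 2 of the 3 splits giving at least as many as the real one, itself included. In direction the real split was the most uneven, with 9 against 38 (80.9% one way), compared with 7 against 12 (63.2%) and 20 against 40 (66.7%). An effect of 4-NP on many transcripts remains open and untested.

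The second pattern was the crowding of the brightest probes on control 2, where the first to the fourth values ran only from 5.93 to 5.80. A compressed bright end of that array may explain it. Over the 12 probes brightest on the other 3 arrays, the slope of control 2 on their mean was 0.468 (95% interval 0.069 to 0.866). The slope was 1.72 (0.16 to 3.28) for control 1, 1.77 (0.98 to 2.56) for 4-NP 1 and 1.48 (0.69 to 2.27) for 4-NP 2, so the interval of control 1 includes the slope of control 2. Measurement error lowers such slopes too, and the predictors of the other arrays include control 2, so part of the contrast is built in. Compression on all 4 arrays stays open, since the ratio of the first to the fourth value (at most 1.17 on the others, 1.02 on control 2) compares different spots, and no biological explanation was tested.

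The third pattern concerned the letters of the probe codes, whose meaning is not given in the sources used here. The 351 probes with codes in V deviated from their own mean over the arrays by a median of 0.11 on control 1, -0.05 on control 2, -0.14 on 4-NP 1 and -0.03 on 4-NP 2 (log2). The 597 probes with codes in M deviated by 0.01, 0.02, -0.01 and -0.08 on the same arrays, and the 237 with codes in MA by 0.04, 0.0021, -0.05 and -0.07. The groups overlapped in the V series and not in the M and MA series. After the median of each letter series was removed, neighbouring codes still deviated together, with a mean correlation over the 4 arrays of 0.075. Of 10000 shuffles of the order within each series the highest gave 0.065, a one-sided permutation p of 1e-04, the smallest they can give. This is consistent with a weak local shift shared by neighbouring codes, which could be the place of the spot on the filter or related genes with adjacent codes. The 2 cannot be separated without a layout or gene names.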
